A study of Canis lupus familiaris with 33 samples.

How the data were processed

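RNA was sequenced from 33 brain samples of 25 dogs, taken at necropsy between 1 and 18 hours after death, per the labels' protocols. The samples were canine oligodendroglioma or brain described as healthy (control), kept either as formalin-fixed paraffin-embedded (FFPE) blocks or frozen at low temperature (fresh-frozen). Groups and dog numbers were read from the labels. Libraries were made with a forward-stranded total RNA kit that adds molecular identifiers of 12 nt and were sequenced as read pairs, per the labels' protocols. Whether reads were collapsed by these identifiers is not given in the sources used here, so counts may hold amplified copies and counting error is only part of the error.

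The deposited values were raw counts of fragments per gene, with no normalisation, made by the authors with featureCounts 1.6.0, per the file headers. The header gave the forward strand option (1), a mapping quality of at least 10, exons grouped by gene identifier, and the Ensembl release 100 gene models of the CanFam3.1 assembly. Chimeric fragments were left out, and no option for fragments of several genes or several positions was set, per the file headers. Genes with near-identical copies elsewhere in the genome can therefore be undercounted. The tools fastp and STAR are named in the submitters' processing notes, and their versions are not given in the sources used here. The table held 30951 genes, of which 30387 lay on chromosomes 1 to 38 and X, 37 on the mitochondrial genome and 527 on unplaced scaffolds. It had 0 entries without a gene identifier, and 750 genes had no count in any library. Total counts ran from 406406 to 32584840 per library, and the low totals limit what could be detected in FFPE tissue.

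The deposited table gives Ensembl identifiers without gene names, and the RefSeq table at hand (assembly UU_Cfam_GSD_1.0) paired 0 of them with a name. The gene lists and cell type markers fixed before the data were examined were therefore not used here. Genes were instead described by chromosome, position, exonic length, number of exons, and membership of the mitochondrial genome or of unplaced scaffolds, classes that were set after the data were seen. Short single-exon features were those with 1 annotated exon of at most 300 bp outside the mitochondrial genome (3344 in the table). Only 4 identifiers are printed, the 2 highest and 2 lowest by the smaller of their 2 fold changes. They were taken from genes that met, in both tumour comparisons, a rule adapted from one fixed before the data were examined. The adapted rule asked for an edgeR adjusted p under 0.05 and an average abundance, as estimated by edgeR, of at least 2 on the log2 CPM scale. It also asked for at least 80% of the libraries of each group on their own side of the median of the other group. The fixed rule named the mean log2 CPM instead and was limited to genes with a name. Of 1972 genes changed the same way in both, 1864 met the adapted rule.

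Most tests, the samples in each fit and most alternatives were also chosen before the data were examined. The tests of chromosomes and of windows of 20 genes were not part of that plan. Nor were the shares of counts in unplaced scaffolds and in the first 2700 bp of the mitochondrial genome. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fits and F tests), with Benjamini-Hochberg adjustment at 0.05. Separate fits compared tumour with control in FFPE and in fresh-frozen tissue. Another fit compared FFPE with fresh-frozen libraries of the same 8 dogs with tissue as a covariate, and the last fit tested the interaction of tissue and preservation over all 33 libraries. Gene classes, chromosomes and consecutive, non-overlapping windows of 20 genes were tested with camera of limma 3.58.1. This was done at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether the genes of a class move on balance in 1 direction, was run beside it. Log2 CPM values used a prior count of 2.

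A chromosome's shift in a library was the median, over its tested genes, of log2 CPM minus the midpoint of the tumour and control means, after subtraction of the library's median over all genes. Tumour and control shifts were compared by two-sided exact permutation over all splits of the libraries, with adjustment over 39 chromosomes. Library measures of the 8 dogs were compared by two-sided exact sign-flip permutation over 256 patterns, adjusted over 9 measures. The pairing by dog was checked from deviations of log2 CPM from the group means. The dog numbers come from the labels and name the animal, and 7 of 8 pairs correlated above 0.1 between preservations, so the fit with the dog as a block is given beside the main one.

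The alternatives were other scaling, DESeq2 1.42.0, limma voom with quality weights, other filters on low counts, mitochondrial genes left out, breed or age as a covariate, subsets of dogs, and the dog as a block. Grade II tumours were left out in another, libraries were thinned to 406406 counts, and each library was left out in turn. For the agreement between preservations, 100 sets of unchanged groups with the same sharing of dogs were simulated from the within-group deviations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. An alternative restricted to protein-coding genes was not run, because the deposited table gives no gene biotypes.

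Every test across genes was checked on simulated counts with 200 genes changed by known folds. With a true fold of 2, 22.1% of the changed genes tested were recovered in the FFPE comparison, 9% in the fresh-frozen comparison, 10.1% between preservations and 1.01% in the interaction. With a true fold of 4 these shares were 86.5%, 70.8%, 64.9% and 35%. Between 2 and 3 unchanged genes were called in each. A simulated shift of 0.5 on chromosome 35 was estimated at 0.55 in FFPE and 0.52 in fresh-frozen tissue. It reached an adjusted exact permutation p of 0.000111 in FFPE and 0.0844 in fresh-frozen tissue, where 6 against 6 libraries allow no single-chromosome p under 0.00216.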

Results

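Oligodendroglioma, a tumour of glial cells, was compared with healthy brain of dogs in 33 RNA sequencing libraries, to ask how far archived FFPE tissue can stand in for fresh-frozen tissue in the search for tumour-associated antigens. The 4 groups were FFPE tumour (11 dogs), FFPE control (10 dogs), fresh-frozen tumour (6 dogs) and fresh-frozen control (6 dogs). The 5 tumour dogs 60636, 60679, 60749, 60127 and 60461 and the 3 control dogs 60460, 60126 and 60462 gave a library of each kind. Total counts (in M, mega-counts) averaged 5.55 ± 3.13 M in FFPE tumours (SD, n = 11), 6.47 ± 9.46 M in FFPE controls (n = 10), 18.7 ± 5.91 M in fresh-frozen tumours (n = 6) and 20.5 ± 4.57 M in fresh-frozen controls (n = 6). The shallowest library was that of FFPE control dog 50315 with 406406 counts, and the deepest that of FFPE control dog 60126 with 32584840. Every pair of libraries within a group differed by more than counting noise, with chi-square values of 18.99 to 539 per degree of freedom, so each library counted as 1 replicate.

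In FFPE tissue, 1342 genes were higher and 1477 lower in tumour than in control brain among 13338 tested with edgeR. On chromosome 13, 70 of 260 tested genes were higher and 20 lower, and on chromosome 35, 41 of 134 were higher and 10 lower. Of the 36 tested features of the mitochondrial genome, 20 were lower and 0 higher, with a median log2 fold change of -1.54. Among the 15 mitochondrial features of at least 200 bp, 1 was lower and the median was -0.12. The camera call for the mitochondrial genome (adjusted p = 1.2e-06) was lost with an estimated correlation (camera adjusted p = 0.949). ENSCAFG00000014040 on chromosome 20 (43234387 to 43289765, 9 exons) had a log2 fold change of 3.77 ± 0.77 (SE; edgeR adjusted p = 0.00265), and 8 of 11 tumours lay above every control. Its group means were 4.58 ± 2.20 log2 CPM in tumours (SD, n = 11) and 0.99 ± 1.77 in controls (SD, n = 10). ENSCAFG00000024883 on chromosome 35 (20099773 to 20101154, 2 exons) had a log2 fold change of 3.60 ± 0.65 (SE; edgeR adjusted p = 0.00136), again with 8 of 11 tumours above every control. ENSCAFG00000012243 on chromosome 26 (22726526 to 22735125, 4 exons) had a log2 fold change of -3.56 ± 0.48 (SE; edgeR adjusted p = 0.000362), with all 11 tumours below every control. ENSCAFG00000044241 on chromosome 7 (497394 to 502952, 5 exons) had a log2 fold change of -3.02 ± 0.57 (SE; edgeR adjusted p = 0.00178), with 10 of 11 tumours below every control. None of these 4 genes overlapped another annotated gene on either strand. Changes of at least 2-fold were held by 869 of the higher and 1112 of the lower genes. The count of 2819 fell to 103 in the 9 tumour and 5 control libraries with a stated age, with age as a covariate. Stated ages ran from 4.7 to 12 years in these tumours and from 2 to 8 years in these controls. Age was thus not balanced, and its part in the calls cannot be fully told apart from that of the tumour. In the 8 dogs that also had a fresh-frozen library the count fell to 1. Which direction was more frequent depended on the setting, with 1518 genes higher and 1417 lower with RLE size factors, 1563 and 1286 with mitochondrial genes left out and 1363 and 2626 without a filter on low counts, while DESeq2 called 52.6% of its 3801 genes higher.

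In fresh-frozen tissue, 2760 genes were higher and 1837 lower in tumour than in control brain among 15057 tested with edgeR. On chromosome 35, 67 of 169 tested genes were higher and 10 lower, and on chromosome 13, 103 of 288 were higher and 30 lower. The mitochondrial genome had 10 of 37 features lower and 0 higher, with a median log2 fold change of -1.22 (camera adjusted p = 1.5e-08, and 0.478 with an estimated correlation). Short single-exon features went the other way, with 67 of 265 higher and 8 lower and a median of 0.88 (camera adjusted p = 0.000803, and 0.514 with an estimated correlation). In the same libraries the share of all counts in short single-exon features was 1.05% ± 0.359 in tumours and 0.543% ± 0.152 in controls (SD, n = 6 each; exact permutation p = 0.00866, adjusted p = 0.0390). ENSCAFG00000014040 had a log2 fold change of 5.05 ± 0.70 (SE; edgeR adjusted p = 0.000961), from 1.74 ± 0.87 log2 CPM in controls to 6.49 ± 1.44 in tumours (SD, n = 6 each). ENSCAFG00000024883 had one of 4.16 ± 0.62 (edgeR adjusted p = 0.00139). ENSCAFG00000012243 was lower by a log2 fold change of -3.47 ± 0.55 (edgeR adjusted p = 0.00158) and ENSCAFG00000044241 by one of -5.16 ± 0.73 (edgeR adjusted p = 0.00104). For each of the 4 genes the 6 tumours and the 6 controls did not overlap, but the genes were picked partly for that separation, so it is no further test of them. The excess of higher over lower genes depended on the setting, with 2360 higher and 2033 lower with RLE size factors, 2910 and 2746 with DESeq2, and 910 and 914 after thinning to 406406 counts.

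The fresh-frozen libraries fell into 2 sets on the second component of their deviations from the group means, which held 23.3% of that variance. The libraries of dogs 60126, 60127, 60461 and 60462 (2 tumour and 2 control, set B) stood apart from the other 8 (4 tumour and 4 control, set A). With the set as a covariate edgeR called 3527 genes higher and 2524 lower in tumour, and 4568 of the 4597 genes called without it were kept. The sets were drawn from these same deviations, and each holds as many tumours as controls. Such a covariate takes up spread and hardly moves the fold changes, so these counts are no test of the tumour effect. Within set A 2291 genes were called. Within set B edgeR called 0 genes, with 4118 at an unadjusted p under 0.05, and no other tool was run on those 4 libraries.

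**Figure D1:**
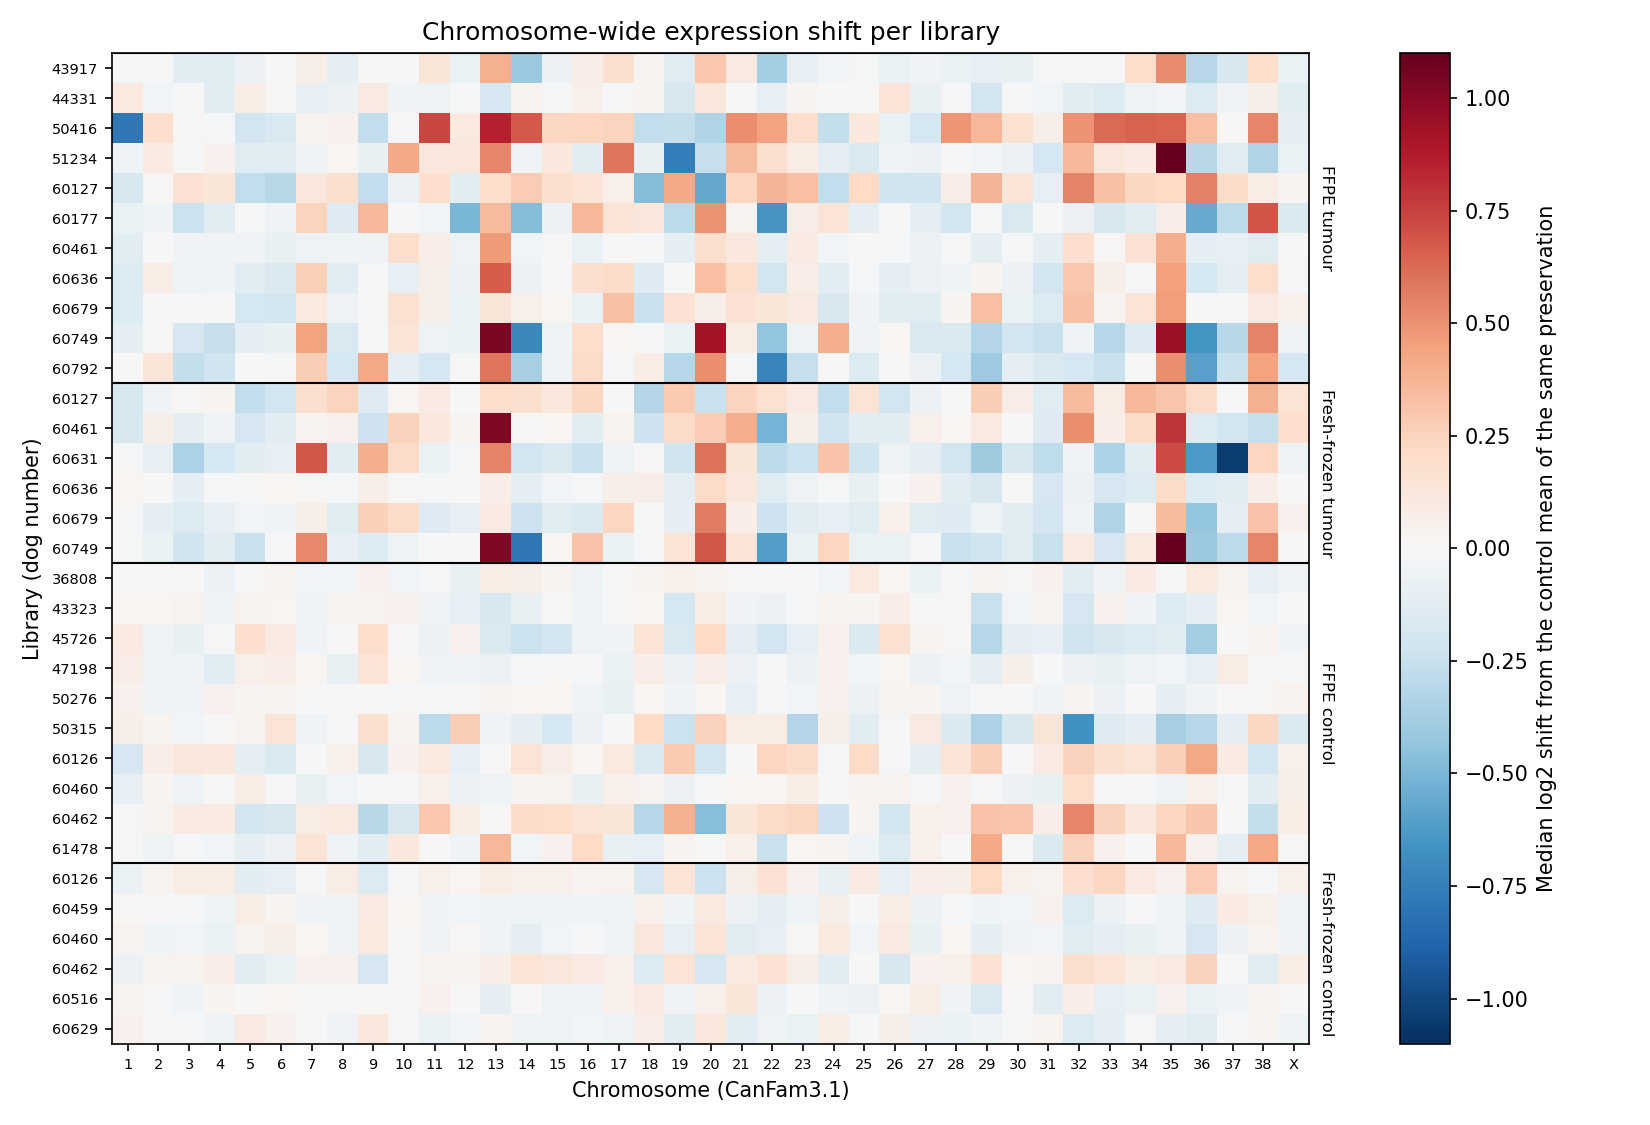
Median log2 shift of each chromosome (horizontal axis) in each library (vertical axis, dog number) from the mean of the controls of the same preservation, red for higher and blue for lower. Chromosomes 13 and 35 were raised in most tumours, with chromosome 13 at 1.02 in the fresh-frozen and 1.04 in the FFPE library of dog 60749.

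Shifts of whole chromosomes were compared next. In FFPE tumours chromosome 13 was shifted by a log2 value of 0.46 and chromosome 35 by 0.50 relative to controls (11 against 10 libraries; adjusted exact permutation p = 0.0150 for both), with 7 and 8 of 11 tumours above every control. In fresh-frozen tumours the shift of chromosome 35 was 0.58 (6 of 6 tumours above every control; adjusted exact permutation p = 0.0422) and that of chromosome 13 was 0.49 (5 of 6; adjusted exact permutation p = 0.0563). Smaller shifts passed the test in 1 preservation only: chromosome 21 at 0.16 (adjusted exact permutation p = 0.0412) and chromosome 27 at -0.11 (0.0150) in FFPE, and chromosome 31 at -0.20 (0.0422) in fresh-frozen tissue. In the other preservation they went the same way, at 0.19, -0.04 and -0.10, and the difference between preservations was not tested. Across the 39 chromosomes, which are not independent replicates, the shifts of both preservations correlated with a Pearson r of 0.878 and a Spearman rho of 0.750. The 8 shared dogs can raise this correlation, and no value for unchanged groups was obtained for it. With camera both chromosomes 13 and 35 passed in both preservations (adjusted p = 0.00108 for both in FFPE, and 0.0385 and 0.00141 in fresh-frozen tissue), and neither call held with an estimated correlation (camera adjusted p = 0.965 in FFPE and 0.960 in fresh-frozen tissue). With fry the adjusted p was 0.0491 for both in FFPE tissue, and 0.178 for chromosome 13 and 0.0202 for chromosome 35 in fresh-frozen tissue. The FFPE calls were lost without a filter on low counts (shifts of 0.05 and 0.11) and without the 8 shared dogs (0.47 and 0.51; adjusted exact permutation p = 0.117 for both), as were both in the 8 shared dogs alone (0.45 and 0.39) and that of chromosome 35 without grade II tumours (0.40). Without that filter the fresh-frozen shifts also fell, to 0.13 for both chromosomes. The smallest p that 6 against 6 libraries can give, 0.00216, adjusts to 0.0844 when 1 of the 39 chromosomes reaches it (exact permutation), so the fresh-frozen call of chromosome 35 needs another chromosome at that p, and it was lost in 12 of 19 alternatives at shifts of 0.47 to 0.69.

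A run of genes between 23 and 26 Mb of chromosome 35 held many raised genes. Of 624 windows of 20 tested genes, 1 passed camera in both preservations, at 24145768 to 25466468 of chromosome 35, with 11 genes higher and 0 lower in FFPE tumours (median log2 fold change 1.06, camera adjusted p = 0.00405) and 13 higher and 0 lower in fresh-frozen tumours (1.16, 0.0160). With an estimated correlation the camera adjusted p was 0.995 and 0.997. The region carries 31 single-exon genes of 4 recurring exonic lengths, 312, 381, 393 and 411 bp, between 23977201 and 25061935. In fresh-frozen tissue 20 of the 23 tested were higher and 0 lower in tumours, with a median log2 fold change of 2.31 ± 0.26 (SE of the median; range 0.83 to 5.06). In FFPE tissue 6 of the 8 tested were higher and 0 lower, with a median of 1.42 ± 0.16. The other genes of the region were higher in 22 of 41 cases in fresh-frozen tissue (median 1.20) and in 15 of 31 in FFPE tissue (median 0.96). Outside the region 25 of 105 tested genes of chromosome 35 were higher and 10 lower in fresh-frozen tumours (median 0.31), and 20 of 95 higher and 9 lower in FFPE tumours (median 0.36). Genes of equal length can be near-identical copies, whose fragments the authors' counting would leave out, so the values of single members are uncertain. The region was singled out after its values were seen.

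**Figure D2:**
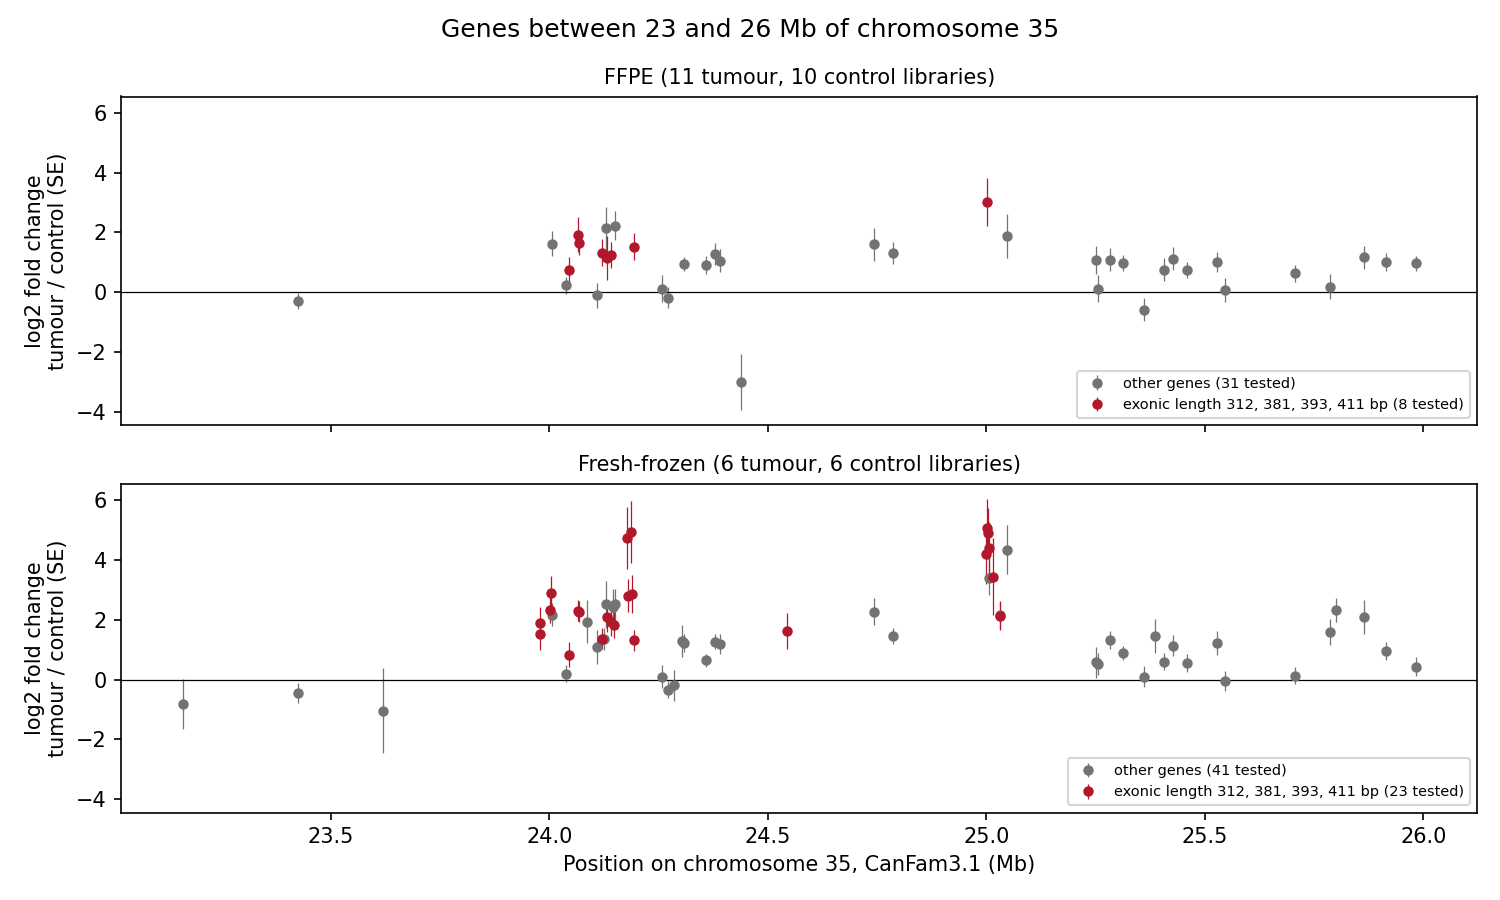
Log2 fold change of tumour over control (vertical axis, with its standard error) for each tested gene by position on chromosome 35 in Mb (horizontal axis), in FFPE tissue above and fresh-frozen tissue below. Single-exon genes of the recurring lengths (red) lay between 0.83 and 5.06 in fresh-frozen tissue.

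Genes that are raised in tumour and low in healthy brain bear most directly on antigen search. With low defined as a mean of under 1 log2 CPM in controls, 70 of 247 such genes were higher in FFPE tumours and 517 of 2168 in fresh-frozen tumours. Over all tested genes 1342 of 13338 were higher in FFPE and 2760 of 15057 in fresh-frozen tumours. A gene this low in controls can pass the filter on low counts through its tumour counts. The numbers tested and the shares higher therefore depend on that filter and on depth. Of 138 genes low in both control groups and tested in both comparisons, 49 were higher in FFPE and 107 in fresh-frozen tumours, and 41 were higher in both, where independent lists would share 37.99. In 18 of the 41 every fresh-frozen tumour lay above every fresh-frozen control, though the 41 were chosen as higher in these libraries. In 0 of the 41 did all tumours of both preservations lie above all controls.

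Tumour effects were then compared gene by gene between preservations. Over 13044 genes tested in both, the log2 fold changes correlated with a Pearson r of 0.833 and a Spearman rho of 0.837, across genes that are not independent replicates. Of the genes higher in tumour, 1121 were shared by FFPE (1341) and fresh-frozen tissue (2494), where independent lists would share 256. Of the genes lower in tumour, 851 were shared by FFPE (1466) and fresh-frozen tissue (1627), where 183 would be shared. A single gene was called in opposite directions. The 1972 genes called the same way made up 70.3% of the FFPE calls and 47.9% of the fresh-frozen calls. Their changes were smaller in FFPE tissue, with medians of 1.19 against 1.51 for higher genes (919 of 1121 larger in fresh-frozen tissue) and -1.30 against -1.58 for lower genes (637 of 851). Because 8 dogs gave libraries to both comparisons, unchanged groups with the same sharing were simulated 100 times. On the log2 CPM scale the simulated correlation averaged 0.242 ± 0.212 (SD) and reached 0.683 at most, against an observed 0.862. The simulated covariance averaged 0.0429 against an observed 0.913, a difference of 0.870. With the FFPE libraries of the shared dogs left out, r was 0.788 over 12765 genes, with 463 higher genes (98.6 for independent lists) and 429 lower genes (90.2) called in both.

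**Figure D3:**
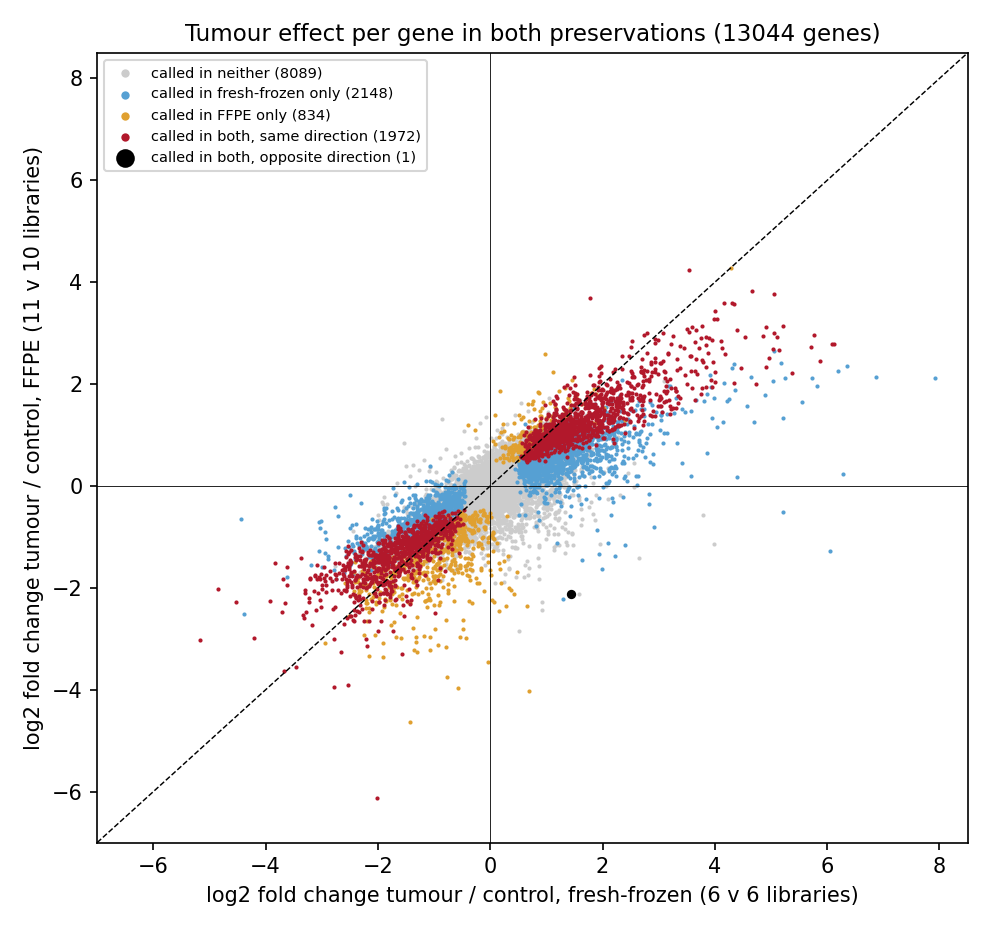
Log2 fold change of tumour over control in fresh-frozen (horizontal axis, 6 against 6 libraries) and FFPE tissue (vertical axis, 11 against 10 libraries), 1 point per gene, with the line of equal change dashed. The 1972 genes called in both with the same direction (red) lie mostly on the side of the dashed line towards the horizontal axis.

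The difference between the tumour effects was also tested directly. In the interaction of tissue and preservation, edgeR called 0 of 15714 genes, with 575 at an unadjusted p under 0.05. DESeq2 called 7, all with a lower tumour effect in FFPE tissue, and limma voom with quality weights called 2, 1 in each direction. As classes, mitochondrial features of at least 200 bp had a higher tumour effect in FFPE tissue, with a median log2 difference of 0.78 over 15 features (camera adjusted p = 1.0e-07), and short single-exon features a lower one, with -0.79 over 714 features (camera adjusted p = 0.00129). Neither held with an estimated correlation (camera adjusted p = 0.622 and 0.804). The simulated interaction recovered 1.01% of 2-fold and 35% of 4-fold differences, so smaller differences were not detectable at this depth and number of dogs.

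Equal numbers of libraries were compared because FFPE tissue had more. In 50 draws of 6 FFPE tumours and 6 FFPE controls, edgeR called a median of 617 genes (0 to 3257), and 0 draws reached the 4597 genes of the 6 against 6 fresh-frozen libraries. The draws called a median of 371.5 genes higher and 270.5 lower in tumour. They equal the number of libraries but not their depth, and with every library thinned to 406406 counts edgeR called 1824 genes in fresh-frozen and 1499 in all FFPE libraries.

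Within the same 8 dogs, the genes higher in FFPE than in fresh-frozen tissue were mostly very short. Among 17097 tested genes, 481 were higher and 23 lower in FFPE tissue, and 343 of the 481 (71.3%) were short single-exon features. The median exonic length of the higher genes was 131 bp and that of the lower genes 1103 bp. Of 793 short single-exon features tested, 343 were higher and 0 lower, with a median log2 fold change of 2.60 (camera adjusted p = 1.2e-76, 0.0357 with an estimated correlation; fry adjusted p = 0.00202). A feature can pass the filter on low counts through its FFPE counts. Without that filter the median was 1.89 over 2751 features, and it was 1.90 over the 164 with a mean of at least 50 counts. The mitochondrial genome had 8 of 37 features higher, with a median of 1.48 (camera adjusted p = 8.3e-14, and 0.193 with an estimated correlation). Single-exon genes over 300 bp had a median of -0.22, with 7 of 781 higher and 3 lower (camera adjusted p = 0.0238, and 0.193 with an estimated correlation). With the dog as a block 571 genes were higher and 84 lower, 420 of the 504 genes were kept, and the short single-exon class had 336 higher and 1 lower (median 2.59; camera adjusted p = 3.8e-58, and 0.262 with an estimated correlation). The count of 504 ranged from 165 without dog 60679 to 773 without dog 60749, and with all 33 libraries and tissue as a covariate edgeR called 2771 genes higher and 2634 lower, so the excess of higher genes was not seen there, while short single-exon features had 620 of 714 higher and a median of 4.24. Of the short single-exon features edgeR called 142 of 738 higher without dog 60679, 171 of 729 without 60636, 219 of 730 without 60127, 228 of 763 without 60461 and 0 of 354 in the control dogs alone (685 of all genes at an unadjusted p under 0.05), with a median of 1.93 there and of 2.22 to 3.05 without any 1 dog.

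Library composition moved the same way. In FFPE libraries of the 8 dogs the mitochondrial share of counts was 24.3% ± 10.1 against 12.3% ± 6.52 in fresh-frozen libraries (SD, n = 8), higher in 7 of 8 dogs (exact sign-flip permutation, adjusted p = 0.0281). Features in the first 2700 bp of the mitochondrial genome took 7.16% ± 4.28 against 1.11% ± 0.939 (8 of 8 dogs; exact permutation, adjusted p = 0.0281). Unplaced scaffolds took 1.16% ± 0.475 against 0.260% ± 0.158 (8 of 8; exact permutation, adjusted p = 0.0281); these FFPE libraries, at 0.152 to 1.47%, lay below all 13 FFPE libraries of other dogs, at 2.59 to 17.6%. Short single-exon features took 2.27% ± 1.97 against 0.843% ± 0.389 (7 of 8; exact permutation, adjusted p = 0.0301). The total was 10.3 ± 9.61 against 21.2 ± 5.57 M counts, lower in FFPE tissue in 7 of 8 dogs (exact permutation, adjusted p = 0.0301). The median exonic length behind the counts was 2966 ± 161 bp against 2998 ± 109 bp, a difference that was within the spread (exact permutation, adjusted p = 0.703).

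**Figure D4:**
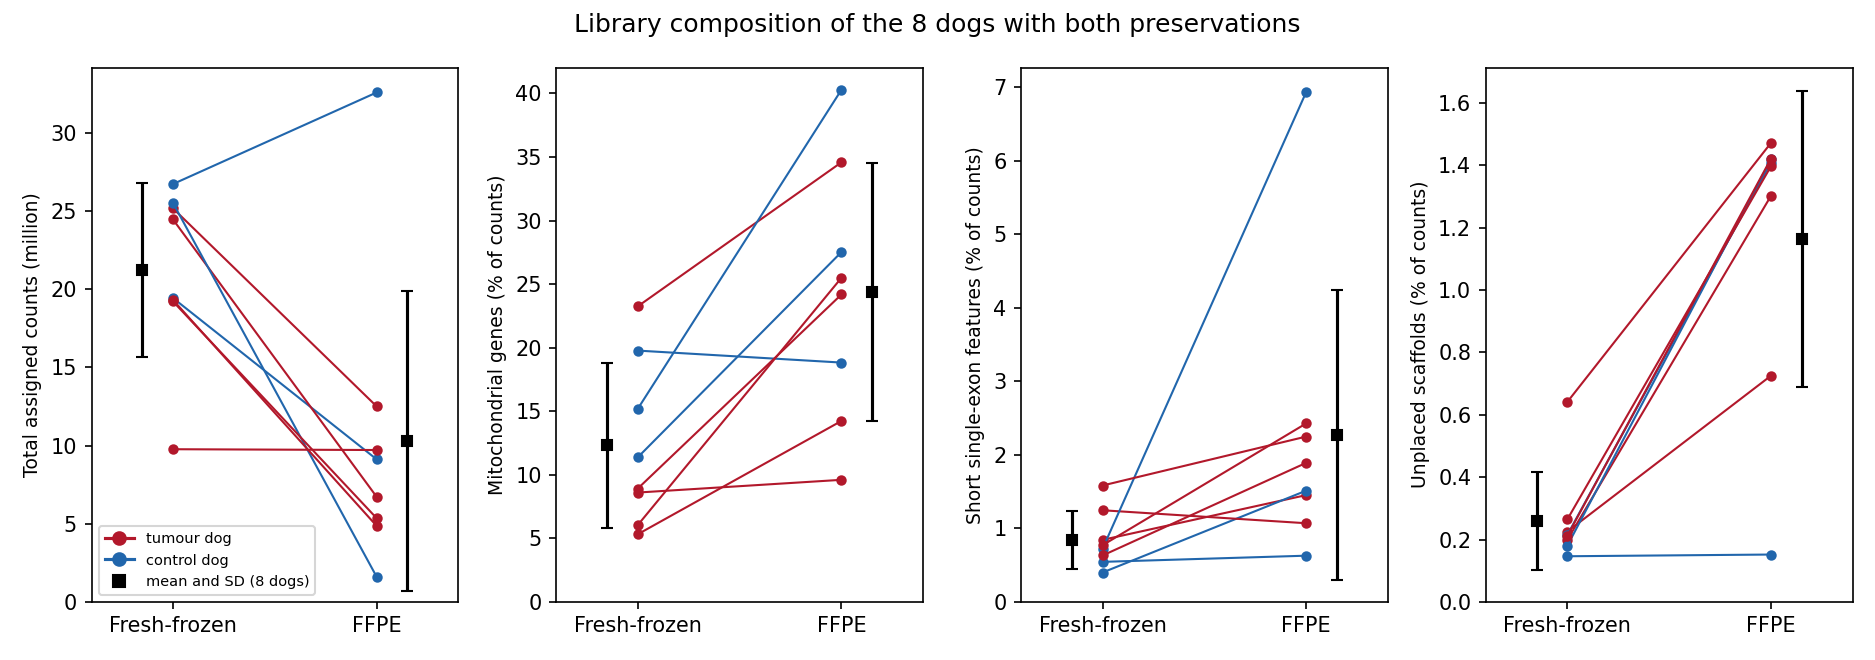
Total counts in M and shares of counts in percent (vertical axes) for the fresh-frozen and FFPE library of each of the 8 dogs (horizontal axis), with lines joining a dog's libraries and squares with bars giving mean and SD. Unplaced scaffolds were higher in FFPE tissue in 8 of 8 dogs and mitochondrial genes in 7 of 8.

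Libraries of the same dog resembled each other across preservations. Deviations of log2 CPM from the group mean correlated with a mean r of 0.406 (0.0641 to 0.748) between the FFPE and the fresh-frozen library of a dog, against -0.124 between different dogs of the same tissue, across 17097 genes that are not independent replicates. Of 720 pairings of the dogs within tissue none other reached this mean (one-sided exact permutation p = 0.00139, the smallest possible). The negative value between different dogs follows largely from subtracting the group means, so the permutation and not that gap measures the resemblance. In 7 of 8 dogs the own library was the closest, the exception being tumour dog 60461 (r = 0.0641). Dogs 60127, 60126 and 60462, which belonged to set B of the fresh-frozen libraries, also lay on its side in FFPE tissue, with projections of 54.3, 48.8 and 52.5 on the same component, while that of dog 60461 was 2.72. Dogs 60679 and 60460 of set A also had positive projections in FFPE tissue (13.2 and 1.39). Among dogs without a fresh-frozen library, FFPE tumour dogs 50416 and 51234 lay at 52.4 and 19.3. FFPE control dogs 61478 and 36808 lay at 11.7 and 1.13.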

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

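The tests of chromosome 13 in other dogs, of thinning to the smallest of 16 libraries, of the region on chromosome 35, of exonic length in general, of the recurring lengths against the rest of chromosome 35, of the interaction's other splits and of dog 60127 left out were chosen only after the results were seen. All gene classes were also set after the data were seen.

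Genes of chromosomes 13 and 35 stood higher in tumours of both preservations by camera, but not with an estimated correlation (camera adjusted p = 0.965 and 0.960), and chromosome 13 missed the permutation test in fresh-frozen tissue (adjusted exact permutation p = 0.0563). A few strongly changed genes on chromosome 13 could not move a median over its genes, whatever the data. Its median shift was 0.47 ± 0.15 in the FFPE libraries of the 6 tumour and 7 control dogs without a fresh-frozen library (SE between libraries; unadjusted exact permutation p = 0.0128). That shift is therefore no separate test of a few genes, and it did not pass after adjustment over the 39 chromosomes. Gene length and expression level are argued against by the 92.4% of the shift left after matching on both. The mean shifts over both chromosomes of 0.53 in set B and 0.56 in set A of the fresh-frozen libraries decide nothing on these sets, since each set holds as many tumours as controls. The genes at 23 to 26 Mb of chromosome 35 stay open as the main source for that chromosome, since without them its shift was 0.20 in fresh-frozen tissue (35.1% left; exact permutation p = 0.0693) and 0.31 in FFPE tissue (61.5% left; exact permutation p = 0.00464). Extra chromosome copies may also account for it, a hypothesis that stays open: the departures of a tumour over the 39 chromosomes correlated between its preservations more than between dogs (one-sided exact permutation p = 0.0417, 5 dogs), but this rests on dogs 60749 (r = 0.881) and 60127 (0.942), as the other 3 (0.192, -0.133 and 0.276) each lay nearer another dog, p was 0.125 without dog 60127, where 0.0417 is the smallest possible, and the FFPE departures of dog 60127 also correlated with the profiles of control dogs 60126 (r = 0.783) and 60462 (r = 0.787).

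Short single-exon features were higher in FFPE than in fresh-frozen libraries of the same dogs, with a median log2 fold change of 2.60. The FFPE library of dog 60462 is argued against by a median of 2.22 without that dog. After thinning the 16 libraries to 1596967 counts each, the median was 2.49 over all 793 features. Thinning keeps the expected share of each feature, and the features were those that passed the filter before thinning. This value therefore does not decide on library depth. An exonic length of at most 300 bp by itself is argued against by multi-exon features of that length. These had a median of 0.26 over 167 features, 2.34 below the single-exon features. The classes were not matched on length under 300 bp, so an effect of still shorter length stays open. Preservation itself, in the tissue or in the library preparation, stays open, and the design cannot separate the tissue from the preparation. No biological explanation was tested.

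Single-exon genes of the recurring lengths on chromosome 35 were higher in tumours, with a median of 2.31 in fresh-frozen tissue. There they exceeded the genes of chromosome 35 outside the region, which had a median of 0.31, by 1.99 ± 0.29 (SE over genes). The difference was 1.26 ± 0.31 in FFPE libraries (SE between libraries; exact permutation p = 0.000261). In those of dogs without a fresh-frozen library it was 0.91 ± 0.38 (SE between libraries; exact permutation p = 0.0361). The region was singled out after the values of all these libraries were seen, so a gap is partly built into that choice. Whether the raised expression of chromosome 35 as a whole is the whole cause is therefore not settled. Other single-exon genes over 300 and up to 450 bp had a fresh-frozen median of 0.87 ± 0.16 (SE over genes), a difference of 1.44. The same choice of region limits this comparison, so it does not settle whether short single-exon genes rose in general. A candidate explanation is a set of core histone genes in dividing tumour cells, a hypothesis from the recurring lengths alone, as the genes are not named. It stays open, because genes of the same lengths elsewhere had a median of 0.86 ± 0.34 in FFPE tissue, but in fresh-frozen tissue their 0.90 ± 0.10 over 12 genes differed by less than its SE from that of other short single-exon genes.

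Of 45 groups of library values tested for a sample far from the others, 8 gave one, where chance gives 2.25. The 11 FFPE tumour libraries were not part of this test, which was run only in groups of at most 10. FFPE control dog 60126 had 32.6 M counts, with the next library at 9.11 M. FFPE control dog 60462 had 20661 genes detected after thinning (next 15011) and 40.3% mitochondrial counts (next 27.5%). FFPE control dog 61478 had a chromosome 13 shift of 0.36 (next 0.08). Fresh-frozen tumour dog 60127 had 23.3% mitochondrial counts (next 8.92%), 30.3% of counts in the top 50 genes (next 17.8%) and 2.71% in the first 2700 bp of the mitochondrial genome (next 0.609%). Fresh-frozen control dog 60462 had 26373 genes detected (next 21486). Whether the many genes detected in both libraries of dog 60462 reflect expression or residual genomic DNA was not tested.

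The tumour effect differed between preservations by camera for 3 gene classes. The median log2 difference, FFPE minus fresh-frozen, was 0.17 for the mitochondrial genome (camera adjusted p = 0.0115), 0.78 for its features of at least 200 bp (1.0e-07) and -0.79 for short single-exon features (0.00129). None of the 3 held with an estimated correlation (camera adjusted p = 0.804, 0.622 and 0.804).

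Other splits of the libraries were fitted to ask whether a random grouping calls as many genes. In FFPE tissue the real split, with 2819 genes, was the only 1 of 100 to reach that count (highest other 49). In fresh-frozen tissue it was also the only 1 of 100, with 4597 genes (highest other 2203, which kept 5 of 6 tumours together). A random grouping is thus unlikely to give either count. For FFPE against fresh-frozen, 2 of 100 exchanges of the preservation labels within dogs reached 504 genes, the real labels included. The other was the exchange of dog 60126 alone, with 532 genes, so a wrong labelling called more genes than the real labels. The libraries of that dog were alike, with 18.8% mitochondrial counts in FFPE and 19.8% in fresh-frozen tissue. Their shares in short single-exon features were 0.629% and 0.545%. Chance is unlikely as the source of the 504 genes but is not excluded. For the interaction the real count was 0 and all 100 assignments reached it (highest other 188), as any assignment must, so these splits say nothing on chance there.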

How the results depend on the processing

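The library sets, the shared dogs as covariate, the doubted control libraries and every setting for chromosome shifts and short single-exon features were added after the data were seen, and the other settings were planned. No direction reversed among the named genes, chromosomes 13 and 35 and the short single-exon class, and other chromosomes and classes were not run. The cause of a moved count was not tested unless fewer samples, fewer genes or fewer counts are named. FFPE tumour against control (2819 genes) gave 5053 with limma voom, 103 with age as covariate in the libraries with an age (both changed at once), and with fewer samples 1 in the shared dogs and 1250 without them. Thinning to 406406 counts gave 1499. The other 31 of 36 settings lay within 1.5 times, and leaving out 1 library gave 2139 to 3385. Without control libraries 50315 and 60462 it was 3270, and 3138 with sharing of the dog as a covariate. Fresh-frozen tumour against control (4597) gave 1824 after thinning, and with fewer samples 391 in the shared dogs, 2291 in set A and 0 in set B. Leaving out 1 library gave 3129 to 5014.

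FFPE against fresh-frozen (504) gave 1135 with DESeq2, 119 with a mean of at least 50 counts (fewer genes), 5405 with all libraries (2771 higher and 2634 lower, against 481 and 23), 76 in tumour dogs, 0 in control dogs and 74 after thinning. With the dog as a block it gave 655. Leaving out a dog gave 165 to 773: 215 without 60636, 165 without 60679, 773 without 60749, 281 without 60127, 269 without 60461, 316 without 60460 and 280 without 60462. The short single-exon median (2.60) was 4.24 with all libraries and 2.16 over the 90 features tested after thinning to 406406 counts. It was 1.89 without a filter on low counts and 1.90 with a mean of at least 50 counts. The interaction (0) gave 7 with DESeq2 and 2 with limma voom, and 0 with the dog as a random block, as a fixed block in the shared dogs, and with disjoint dogs.

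The correlation of tumour effects stayed between 0.788 and 0.856 and the same-dog correlation between 0.372 and 0.446 (largest exact permutation p = 0.00417). Draws of 6 against 6 without control 50315 gave a median of 682.5. Each of the 4 named genes kept its direction in all settings, and missed the threshold in 1 to 3 of 35 or 36 FFPE settings and, in fresh-frozen tissue, in set B alone. The fresh-frozen call of chromosome 35 was lost without tumour 60631, 60679 or 60749 or any 1 control, with shifts of 0.47 to 0.69, and kept without a filter, where it shifted by 0.13 and chromosome 13 by 0.13. That of chromosome 13 was gained in 4 of 19 settings, among them without tumour 60636 (0.58) or 60127 (0.56). In FFPE tissue chromosome 35 also missed the threshold without grade II tumours (0.40), and both chromosomes in the shared dogs alone (0.45 and 0.39). Protein-coding genes alone and the gene lists were not run.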

Other observations

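The tests and values of this part were chosen after the data were seen.

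Single tumours departed from the control mean on further chromosomes. Dog 60749 had chromosome 20 at 0.68 in its fresh-frozen and 0.91 in its FFPE library, chromosome 22 at -0.62 and -0.43, and chromosome 36 at -0.41 and -0.66. Dog 60127 had chromosome 20 at -0.25 and -0.56 and chromosome 36 at 0.21 and 0.56. Control dogs 60126 and 60462 showed the same directions in FFPE tissue, with chromosome 20 at -0.21 and -0.47 and chromosome 36 at 0.42 and 0.30. In fresh-frozen tumours chromosome 20 had 216 of 723 tested genes higher and 49 lower, with a shift of 0.35 that did not pass the adjusted exact permutation test (p = 0.194; 5 of 6 tumours above every control), while its camera adjusted p was 0.00816, and 0.960 with an estimated correlation. Windows of 20 genes that passed camera in 1 preservation lay at 18729234 to 22624987 of chromosome 13 in FFPE tissue (10 higher, median 0.74; camera adjusted p = 0.0279, and 0.995 with an estimated correlation) and at 16644 to 424264 of chromosome 10 in fresh-frozen tissue (11 higher, median 0.97; camera adjusted p = 0.0319, and 0.997 with an estimated correlation).

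In fresh-frozen libraries the median exonic length behind the counts was 2914 ± 73.8 bp in tumours and 3120 ± 102 bp in controls (SD, n = 6 each; adjusted exact permutation p = 0.0390). In FFPE libraries it was 2941 ± 126 bp (n = 11) and 2953 ± 135 bp (n = 10; adjusted exact permutation p = 0.949). Unplaced scaffolds took 0.332% of counts in fresh-frozen tumours and 0.190% in controls (n = 6 each; adjusted exact permutation p = 0.0455).

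Both libraries of control dog 60462 held counts in many genes that were near silent elsewhere. Of 5294 genes with at most 1 count in all other fresh-frozen libraries, 2746 had counts in its fresh-frozen library, with a median of 2 counts, while at most 417 such genes were found in another library. Of 3544 such genes in FFPE tissue, 2085 had counts in its FFPE library, with a median of 3, against at most 288 in another library. Mean counts rose with exonic length with slopes of 0.758 ± 0.0414 and 0.898 ± 0.0496 (SE) on log scales over 10 length bins. Whether these counts are expression or residual genomic DNA was not tested.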
